A study of Drosophila melanogaster with 4 samples.

How the data were processed

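Total RNA of Drosophila melanogaster embryos was compared on 4 Agilent 2-colour arrays, each holding 1 extract of embryos without the 8-miR cluster and 1 extract of w1118 embryos. This follows titles and source names, while other label fields name a miR-8 cluster null and an ectopic mir-3, so the labels conflict on the genotype. Per the labels, flies laid eggs for 2 h, embryos were aged for 6 h at 25 degrees C, and the stage was 6 to 8 h after egg laying. The design text states 3 biological replicates per genotype, isolated independently. Replicates 1, 2 and 3 carried the null in Cy3 and w1118 in Cy5. A 4th array held replicate 1 again with the dyes exchanged, so replicates 2 and 3 exist in 1 dye orientation only. The arrays lay on 2 slides: slide 1 held both arrays of replicate 1, and slide 2 held replicates 2 and 3.

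Per the file headers, the authors scanned the arrays and extracted spots with Agilent Feature Extraction 10.1.1.1. The deposited intensity columns used here were the median spot brightness in each channel and the median local background, neither of them normalized. The deposited processed intensity was background-subtracted and dye-normalized per the file headers, and the deposited log ratio was the log10 of its Cy5 over its Cy3 value. The authors' series matrix held log2 values whose scale, centring and direction were not stated. Set against the scanner files, its 4 columns followed the log2 ratio of processed signals with a slope of 1.00 and ran wild type over null, with medians of -0.137, 0.071, 0.128 and -0.041. Processed signals and matrix gave the same median over genes, 0.014 as null over wild type. No centring beyond that of the processed signals was thus seen.

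The main values were planned from mean spot signals, and median signals took their place because the files used here carry medians. Background was corrected with limma 3.58.1 under R 4.3.3 (normexp, offset 50), and ratios were normalized within each array by loess with control and outlier spots at weight 0. Every ratio was turned to null over wild type by the dyes in the labels. Spots of one probe were averaged, and outlier-flagged spots were left out. A probe was kept if it was well above background in the same genotype in at least 2 of the 3 replicates. A gene was represented by its kept probe with the highest mean signal. The 2 arrays of replicate 1 were averaged first, which gave 3 replicates.

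Of 32162 probes, 19471 were named for 13052 genes through annotation IDs and RefSeq accessions in a table of the Release 6 assembly, and 12691 were not named. The array design used an earlier build, so the table served only for names and for gene order. Of the probes, 19758 were kept, 14232 of them named, and 9732 genes were tested. Fits used limma's lmFit and eBayes with an intercept, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. A gene with no probe well above background in 1 genotype was given a bound, from channel signals after loess and Aquantile against, on each array, the lowest signal well above background or the dim probe's own signal, whichever was higher. Where the probe's own signal was the higher on every array, the bound equals the fitted fold. Bounds carry no interval. Such bounds are open to dye bias, since 2 replicates had no swap.

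Gene lists were fixed before the data were examined. They were tested with camera at an inter-gene correlation of 0.01 where at least 5 genes were measured, which held for 28 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera rests on the few residual degrees of freedom of 3 replicates, so it had little power here. Genes were named by a rule fixed before the data were examined: Mef2, w, the nearest gene on either side of the cluster, the 12 highest and 12 lowest called ratios with one sign in all 3 replicates and measured above background, and up to 4 called members of each list. Nearest was applied as nearest measured, and above background as above it in both genotypes. Outside the rule, the genes with a bound among the largest, Trpm, further neighbours of the cluster and the examples of neighbouring pairs were chosen after their values were seen. Alternatives covered background correction, normalization, the filter, the probe summary, the dye swap, the test, the slide, array weights and each replicate left out.

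The pipeline was tested on simulated data with 50 genes changed at each size among the 9732 genes of this comparison. It recovered 38% of genes changed 1.2-fold, 96% at 1.5-fold, and 100% at both 2-fold and 4-fold, with 1 false call among 168. The simulated dye bias was chosen, not fitted to these arrays, and all probes had 1 noise level. In the real data 646 of 5321 calls had the opposite sign on the dye-swap array. The simulated share of false calls therefore does not carry over to the real calls. On 58.01% to 65.47% of green spots and 56.71% to 65.79% of red spots the signal was well above background. The number of arrays limits the precision. Seed matches of the deleted microRNAs in 3' UTRs, and distances in bases from the cluster, were not analysed here. Figures were drawn with matplotlib under Python.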

Results

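Embryos lacking the 8-miR cluster, a group of microRNA genes on chromosome arm 2R, were compared with w1118 embryos, a white-eyed laboratory strain, at 6 to 8 h after egg laying. The series title names Mef2, the transcription factor that drives muscle differentiation, as the gene whose level the deletion affects. Each of 3 replicates paired 1 extract of each genotype, and replicate 1 was hybridised a second time with exchanged dyes. Ratios are log2 of null over wild type, with SD over 3 replicates, and run opposite to the authors' matrix values. None of the 8 cluster microRNAs had a named probe (0 of 8), so the arrays did not check the deletion itself.

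Across 19751 kept probes, ratios of the 3 unswapped arrays correlated with one another at Pearson's r of 0.941 to 0.958, while the dye-swap array correlated with them at 0.824 to 0.883. The rank correlations were 0.872 to 0.899 among unswapped arrays and 0.559 to 0.634 with the swap. These are correlations across probes, which are not independent replicates. Of 9732 genes tested, 2731 were higher and 2590 lower in the null (limma, adjusted p under 0.05). Most differences were small: 183 genes were higher and 181 lower by at least 2-fold. These counts depended on the processing: they were 450 and 466 with the scanner's processed signals, and 324 and 353 with normexp offset 0. In the main fit, all 364 of these kept their sign on the dye-swap array. Among the 2049 calls under 1.2-fold, 389 had the opposite sign there, so 81.0% agreed. At 1.2 to 1.5-fold 247 of 2206 were opposite, and 646 of all 5321 calls. The dye-swap array is part of the replicate 1 mean, so its agreement is not independent of the calls. With replicate 1 taken from its swap array alone, 1746 genes were higher and 1678 lower. Over 20 alternatives the higher count ran from 1059 to 3383 and the lower from 1017 to 3209, fewest in an ordinary test without moderation. Without replicate 3 they were 1765 and 1710.

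Mef2 (CG1429) did not pass the test by its brightest probe, with a ratio of -0.04 ± 0.12 (SD, n = 3; 95% interval -0.18 to 0.10, limma adjusted p = 0.615). Its 5 probes above background disagreed. Probe A_09_P013321, named for the same transcript RD as the brightest, gave 0.73 ± 0.09 (limma adjusted p = 7.99e-05) and was positive on each of the 4 arrays. Adjusted p-values of these further probes are from limma over all kept probes. The 2 probes named for transcript RF rose by less, at 0.22 ± 0.03 (adjusted p = 0.00862) and 0.16 ± 0.07 (adjusted p = 0.0365). The probe named for RB gave -0.10 ± 0.03 and did not pass (adjusted p = 0.125). With the mean of the kept probes, Mef2 was called higher at 0.20 (adjusted p = 0.00627).

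**Figure D1:**
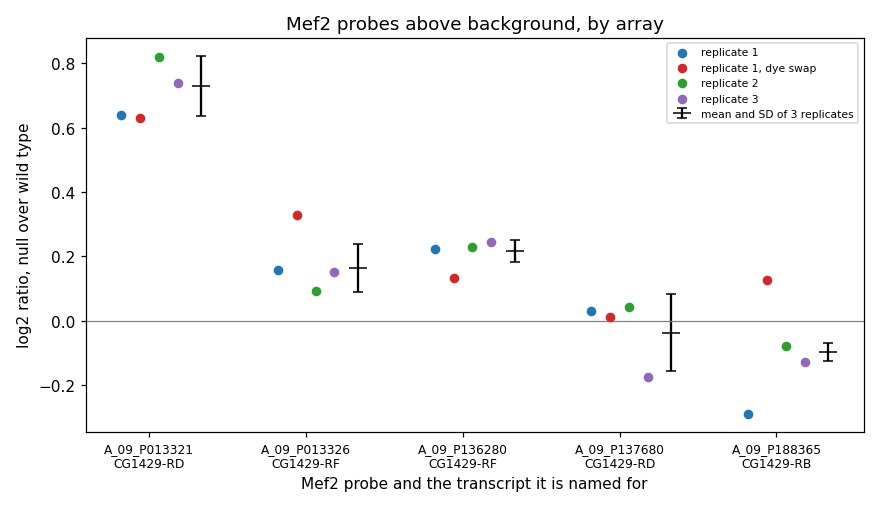
Log2 ratio of null over wild type (vertical axis) for the 5 Mef2 probes above background (horizontal axis), with 1 point per array and bars for the mean and SD of 3 replicates. Probe A_09_P013321 lies between 0.63 and 0.82 on all 4 arrays, while the brightest probe, A_09_P137680, lies between -0.17 and 0.04.

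Among genes whose called probe was above background in both genotypes, the largest decreases were in CG18754, whose signal was 75.7-fold higher in wild type (-6.24 ± 0.09, adjusted p = 5.00e-08), and in the mucin gene Muc18B (-5.41 ± 0.21). The Drosomycin-like gene Drsl5 followed at -5.21 ± 0.08 and CG9498 at -5.18 ± 0.15. Further down in this group were ssx (-4.47 ± 0.07), the UDP-glycosyltransferase Ugt50B3 (-4.31 ± 0.05), the mitochondrial peroxiredoxin Prx3 (-3.78 ± 0.22), the Wnt pathway gene Apc (-3.52 ± 0.06) and Arc1 (-3.33 ± 0.06). The lysozyme genes LysE (-3.23 ± 0.05) and LysD (-3.15 ± 0.05) are close copies, so their values are uncertain. A 2nd probe gave -4.97 for Muc18B, -3.38 for Drsl5 and -3.45 for Prx3. In mwh the called probe gave -3.03 ± 0.08 and another 0.25, and in ssx a 2nd probe gave 0.91, opposite in sign. Trpm, named after its values were seen, gave -4.05 by a called probe not above background in the null, while its 4 other kept probes gave -0.07 to 0.25.

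In the same group, the largest increases were in htt, the fly huntingtin gene, at 14.0-fold (3.81 ± 0.05, adjusted p = 9.45e-08), and in the activin ligand Actbeta at 13.0-fold (3.70 ± 0.09). CG4467 rose at 3.67 ± 0.21, the glutathione S-transferase GstE11 at 3.59 ± 0.27, and the gap gene Kr at 3.46 ± 0.17. CG10859 (3.39 ± 0.06), CG5773 (3.38 ± 0.09), Dus2 (3.28 ± 0.03) and sfl, a heparan sulfate enzyme (3.21 ± 0.04), were close behind. CG11883 (3.16 ± 0.29), CG8607 (3.14 ± 0.11) and CG4679 (3.07 ± 0.27) completed the 12. The other 5 kept probes of CG4467 gave 0.95 to 3.23. A 2nd probe gave 1.40 for CG10859 and 1.35 for CG11883, neither above background in wild type on any array. For CG4679 a 2nd probe, above background in both genotypes, gave 0.26. All 24 genes passed under every alternative in which they were measured, but their order and sizes depended on the processing. With the scanner's processed signals or the authors' matrix CG9498 was lowest of the 24 and CG11883 highest. Over the alternatives CG9498 ran from -6.985 to -5.099, CG11883 from 2.254 to 5.116, CG18754 from -6.559 to -6.192 and htt from 3.78 to 4.374.

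**Figure D2:**
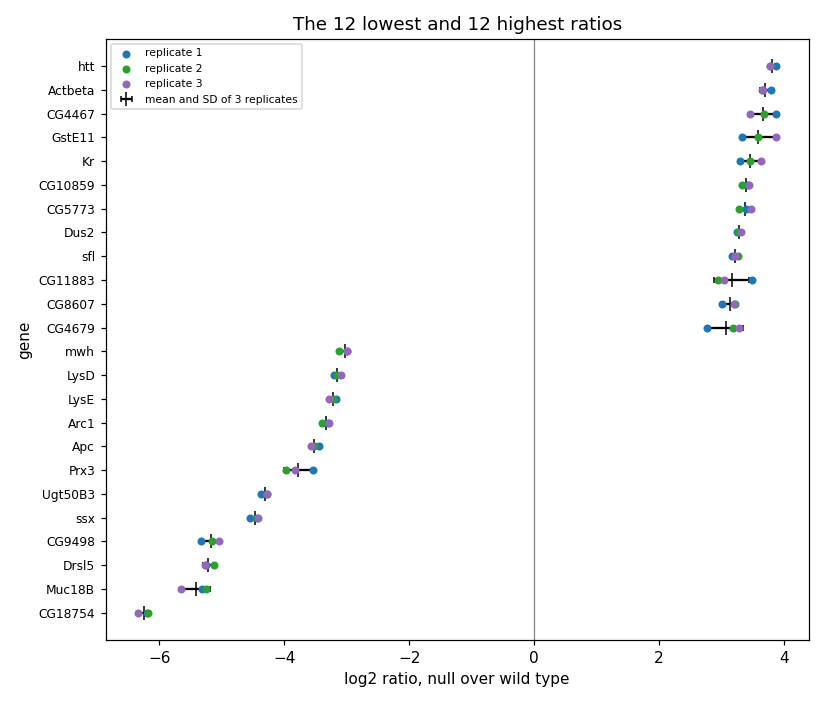
Log2 ratio of null over wild type (horizontal axis) of the 12 lowest and 12 highest genes (vertical axis), with a point per replicate and bars for the mean and SD of 3 replicates. The ratios run from -6.24 for CG18754 to 3.81 for htt, and the replicates of each gene lie on the same side of 0.

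Genes with no probe well above background in 1 genotype have a bound there. Genes such as Trpm, with another probe above background in both, have none. The 3 largest bounds on each side are named, chosen after their values were seen. The odorant receptor gene Or19a was at least 18.01-fold higher in the null (adjusted p = 1.47e-07), Met75Ca at least 9.04-fold and Sid at least 7.36-fold. A 2nd probe of Sid gave 2.12-fold (log2 ratio 1.09), also with no wild-type signal above background. Kap3, a kinesin-associated protein gene, was at least 30.1-fold lower in the null (adjusted p = 9.20e-08), Ir52c at least 10.06-fold and CG32572 at least 6.66-fold. These bounds lie close to the fitted folds and take no account of the spread. The log2 95% interval was -3.59 to -3.09 for Ir52c and -2.995 to -2.542 for CG32572. Folds smaller than the bounds are therefore not excluded. In all, 82 called genes were higher with no wild-type signal well above background, and 73 were lower with none in the null.

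The eye pigment transporter gene w was lower in the null at -2.64 ± 0.25 (adjusted p = 3.24e-06), and a 2nd probe gave -1.44 ± 0.14. Its mean log2 signal was 9.17 in wild type and 6.53 in the null, and the brightest probe was above background on all 4 arrays in both. The labels give the white-eyed w1118 background for both genotypes and name no w marker, so what this ratio means is left open. The direction of every ratio rests on the dyes in the labels, which no probe of a deleted gene could check, and exchanged labels would turn every sign. Beside the cluster, CG15125 was at least 1.17-fold lower, with no signal above background in the null (adjusted p = 0.00695; not past the threshold without moderation, at 0.0628). That bound equals the fitted fold, whose log2 95% interval was -0.33 to -0.11, so it takes no account of the spread. On the other side CG11018 was at least 3.26-fold lower (adjusted p = 1.76e-05), again the fitted fold, with a log2 95% interval of -1.92 to -1.49. Of the 5 nearest measured genes on each side, a tally made after the values were seen, 7 of 10 were called lower and 0 higher. Those named here by the same late choice are hrg, Kpc2, sm and CG11007. By its brightest probe hrg gave -0.01 ± 0.07 and did not pass, though 2 of its 3 other kept probes passed lower at -0.26 and -0.39 (limma over all kept probes, adjusted p = 0.00748 and 0.0016). On that side Kpc2 fell at -0.99 ± 0.22 (others -1.19 to -0.67), and on the other sm at -0.31 ± 0.04 (2nd probe -0.80) and CG11007 at -0.84 ± 0.03. On the cluster's arm 1157 of 1980 genes were called (58.4%), against 4164 of 7752 elsewhere (53.7%; Fisher's exact test, two-sided, p = 0.000164, adjusted p = 0.00131 over 8 tests). Of the other large arms, 2L had 56.8% called and X 49.8%. At least 2-fold different were 4.3% on the cluster's arm and 3.6% elsewhere, which did not pass (Fisher's exact test, p = 0.145). Among the 100 nearest measured genes the share was 58.0%, and Fisher's exact test did not pass (p = 0.545). Genes are not independent in these tests.

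Of 28 gene lists, 3 were called by camera at a correlation of 0.01, each lower in the null, and 0 with an estimated correlation (adjusted p = 0.841 for each of the 3). The latter version had little power, having few residual degrees of freedom. For muscle structure the estimated correlation was -0.018, under 0.01, yet the unadjusted camera p rose from 0.000507 to 0.0577. For this list, losing the call in that version therefore does not show that correlated genes produced it. The estimated correlation was 0.099 for ribosomal proteins and 0.1 for the follicle cell list, both above 0.01. For these 2 lists a part of correlated genes in the call stays open. Muscle structure genes had a median of -0.32: 19 of 32 fell, 6 rose and 7 did not pass, with the same counts adjusted over the list alone. Strn-Mlck (-0.90 ± 0.16), the myosin light chain Mlc1 (-0.87 ± 0.13), the troponin I gene wupA (-0.72 ± 0.09) and the myosin heavy chain gene Mhc (-0.69 ± 0.19) fell most by their brightest probes. The other 6 kept probes of Strn-Mlck gave only -0.31 to 0.05, while those of wupA gave -0.78 to -0.53 and those of Mhc -0.68 to -0.57. With the mean of kept probes the list's median was only -0.17. The list passed camera at a correlation of 0.01 under that and all other alternatives, 20 in all (highest adjusted p = 0.0459). Camera gave adjusted p = 0.00709, and adjusted p = 0.841 with an estimated correlation. The median was -0.31 on slide 1 and -0.33 on slide 2.

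Follicle cell, chorion and yolk protein genes, which serve egg formation in the mother, had a median of -0.39, with 10 of 16 lower and 2 higher, the same adjusted over the list alone. The vitelline membrane gene Vm26Aa fell at -2.05 ± 0.06, the chorion gene Cp15 at -1.10 ± 0.08 and the yolk protein gene Yp2 at -1.06 ± 0.15. Vm32E, with no signal above background in the null, was at least 2.39-fold lower. This bound equals its fitted fold, whose log2 95% interval was -1.36 to -1.15. Camera gave adjusted p = 0.00725, and adjusted p = 0.841 with an estimated correlation. The median was -0.45 on slide 1 and -0.38 on slide 2. With probes required above background in both channels on all arrays, only 6 of the genes were left, with a median of -0.25, and the call was lost (adjusted p = 0.0996). Over 20 alternatives the median ran from -0.921 to -0.163.

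Ribosomal protein genes had a median of -0.17, with 44 of 87 lower and 7 higher, and 45 lower adjusted over the list alone (camera adjusted p = 0.00403, and adjusted p = 0.841 with an estimated correlation). RpL28 gave -0.72 ± 0.14 by its brightest probe and 0.11 by a 2nd, while RpS28-like rose at 1.28 ± 0.06. The list's median was -0.16, -0.22 and -0.20 on the unswapped arrays and 0.02 on the dye-swap array. It was -0.08 on slide 1 and -0.21 on slide 2. The call was lost with the scanner's processed signals (median -0.04, adjusted p = 0.527) and without replicate 2 (median -0.15, adjusted p = 0.529).

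The other 25 lists did not pass camera, and their counts are of single genes. Adjusted over each list alone the counts were the same, except in 4 lists given below. Ratios of single genes are from the brightest probe. Among mesoderm and muscle regulators 8 of 34 rose and 13 fell: Kr rose, mid fell at -1.40 ± 0.07 (2nd probe -0.64), and sna, a mesoderm-determining repressor, rose at 1.14 ± 0.12 (2nd probe 1.44). Of 17 myoblast fusion genes 5 rose and 1 fell, with blow at 0.54 ± 0.10 (others 0.21 to 0.73) and sns at 0.41 ± 0.06 (2nd probe 0.15). Neuroblast and neuronal genes had 14 of 29 lower and 4 higher (camera adjusted p = 0.067). The list was called lower under 6 of 20 alternatives (adjusted p = 0.0156 to 0.0461), though not with an estimated correlation (adjusted p = 0.841). Those 6 are not all separate: processed signals and the authors' matrix, as given and centred, rest on the same ratios. Of 15 gap and terminal patterning genes 7 fell and 1 rose, with pdm2 at -1.27 ± 0.19, where a 2nd probe gave only -0.15, and btd at -1.20 ± 0.09, where a 2nd gave -1.33. Pair-rule and segment polarity genes had 9 of 21 lower and 2 higher, and passed camera as lower only with a dye term (adjusted p = 0.0461; 0.841 in the main fit with an estimated correlation). The dye term was fitted over the 4 arrays, so the extracts of replicate 1 counted as 2 arrays there. Dorsoventral and amnioserosa genes had 7 of 14 lower and 1 higher, with rho at -0.56 ± 0.06. Of 8 Hox genes 4 fell and 1 rose, and of 7 blastoderm cellularisation genes 2 fell and 1 rose.

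Maternal effect and egg activation genes went both ways, with 12 of 41 higher and 10 lower, as did germ plasm and pole cell genes with 9 higher and 9 lower of 24. The actin nucleator gene spir fell at -1.73 ± 0.17 by 1 probe, while its 3 others gave -0.15 to -0.03 and did not pass. Further, bcd rose at 0.85 ± 0.09 (2nd probe 0.66) and osk fell at -0.65 ± 0.07. Of 24 hemocyte genes 6 rose and 6 fell, with the peroxidasin gene Pxn at 1.41 ± 0.06 (others 0.29 and 0.58) and PPO1 at 1.41 ± 0.18. Of 12 glia genes 2 rose and 3 fell, with pnt at 1.08 ± 0.04, where the others gave 0.99 and -0.33. Trachea and salivary gland genes had 4 of 21 higher and 6 lower, with PH4alphaSG2 at 2.07 ± 0.02. Late cuticle and chitin genes had 12 of 26 lower and 6 higher, with Gasp at -0.89 ± 0.08. Of 14 endoderm and gut genes 3 fell and 1 rose, and only 1 fell when adjusted over the list alone.

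Heat shock genes had 7 of 17 lower and 6 higher, with Hsp68 at 0.96 ± 0.08. Of 25 ecdysone pathway genes 9 rose and 4 fell, of 18 apoptosis genes 3 rose and 5 fell, and of 29 cell cycle and replication genes 7 rose and 2 fell. Of 15 antimicrobial peptide and immune recognition genes 4 rose and 5 fell, Drsl5 among them, and the list passed camera only without replicate 2 (adjusted p = 0.0352; 0.87 in the main fit with an estimated correlation). Enhancer of split and Bearded complex genes had 4 of 16 higher and 3 lower (2 lower over the list alone). MicroRNA pathway genes had 3 of 14 higher and 2 lower (2 higher over the list alone), and dosage compensation and sex determination genes 4 of 17 higher and 4 lower. As markers of adult tissues, 8 adult head and eye genes had 2 higher and 2 lower, and 5 testis and male accessory gland genes had 3 higher and 1 lower (4 higher over the list alone).

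**Figure D3:**
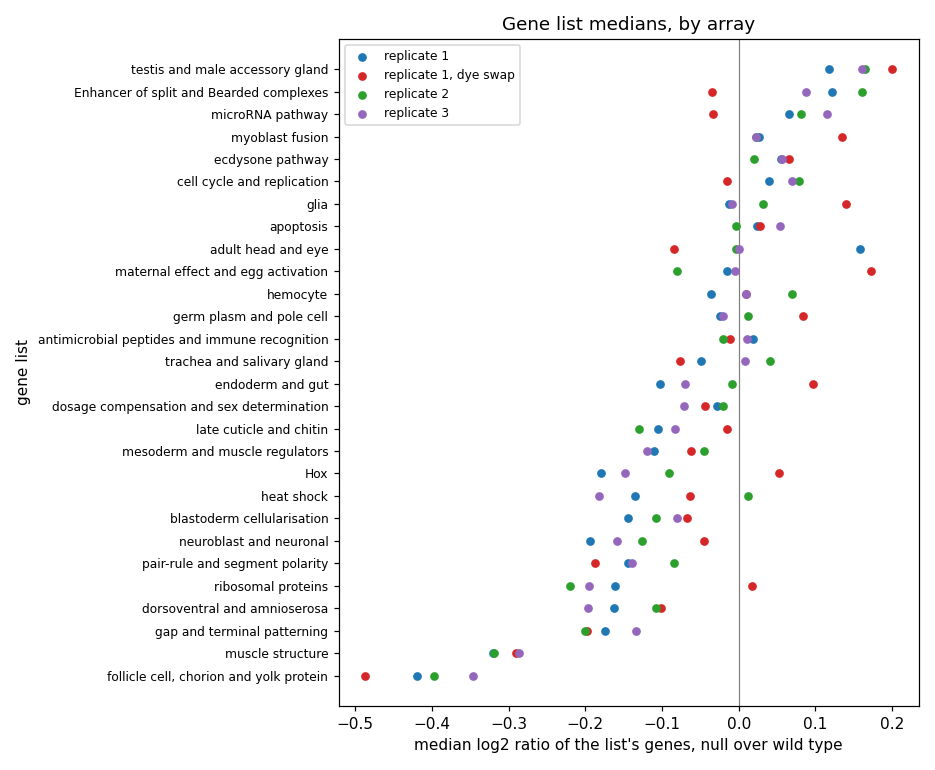
Median log2 ratio of null over wild type (horizontal axis) of each of 28 gene lists (vertical axis), with 1 point per array. Muscle structure and the follicle cell list lie below 0 on all 4 arrays, as do several lists that were not called, such as gap and terminal patterning. Ribosomal proteins lie at 0.02 on the dye-swap array.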

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

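The tests of dye bias in large ratios and in Mef2, of a shared Mef2 rise and of embryo age were chosen after the results were seen. Of 75 quantities compared over the 4 arrays, 7 had 1 array far from the rest, 5 of them the dye-swap array, and chance gives about 1 in 20. Replicate 3 gave -0.175 for the brightest Mef2 probe against 0.011 to 0.044 elsewhere. The swap array gave 3.908 for Actbeta, 2.80 for CG8607, -5.278 for Kap3, 0.131 for Mef2 probe A_09_P136280 and 0.135 for the myoblast fusion median. The share of log ratios within 0.01 of the recomputed value was 99.994% on replicate 1 and 100% on the others.

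The title's gene, Mef2, had probes that moved apart. Dye bias is argued against by the rising bright probe, which gave 0.629 on the dye-swap array. Background correction and normalization are argued against too, since the gap between the 2 brightest probes was never below 0.766 under them. A rise of all Mef2 transcripts alike would have to lift the brightest probe, whose 95% interval ended at 0.105. A change in transcript form, a sequence difference under a probe and cross-hybridisation stay open, because probe sequences were not analysed here.

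Many large differences rest on 1 probe. Of 111 genes called at least 2-fold different that had a 2nd kept probe, 46 (41.4%) agreed in sign with at least 0.5 of the log2 size, against a mean of 3.39 when probes of other genes were drawn. Where the 2nd probe's signal was within 4-fold of the 1st, 41 of 79 (51.9%) agreed. A further 253 such genes had no 2nd kept probe. Dye bias is argued against by the swap array, on which 100% of the large calls kept their sign. That array also entered the calls through replicate 1, so this agreement is partly built in. A difference at one probe's target, such as a strain variant or a transcript form, may account for part of the other genes, and these shares leave this open. Whether the deletion or the strain changed a gene was not tested.

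Muscle structure genes were lower as a list by camera at a correlation of 0.01, but did not pass with an estimated correlation (adjusted p = 0.841). That 2nd version had little power with 3 replicates, so its result decides little. Dye bias is argued against by a median of -0.29 on the dye-swap array. The choice of 1 probe per gene stays open, since the median shrank to -0.169 with the mean of kept probes, though the list passed camera at a correlation of 0.01 under all 20 alternatives (highest adjusted p = 0.0459). Younger null embryos could also lower these genes, but lists of early patterning genes did not pass in either direction (lowest camera adjusted p = 0.142). With a dye term the pair-rule and segment polarity list was called lower (camera adjusted p = 0.0461), the direction opposite to that predicted for younger embryos. That fit took the 4 arrays singly, so the extracts of replicate 1 counted as 2 arrays, and its call decides little. In the main fit with an estimated correlation, camera gave this list adjusted p = 0.841. As the main fit and the other alternatives gave no such call, embryo age stays open. An effect of the deletion stays open as well, as untested.

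Turning the sign of 1 replicate gives 4 patterns, too few for a share under 0.05. Only 1 of the 4, the real one, called as many as 5321 genes, and the highest other called 0. For gene lists the real pattern called 3 and the highest other 2, so again 1 of 4 reached the real count.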

How the results depend on the processing

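The centred matrix values, single Mef2 probes, windows by gene order and counts at 2-fold were chosen after seeing the data. Calls with opposite signs in the main and another setting occurred only with the mean of kept probes (23 genes), among the settings run. Of 136 named genes other than Mef2, 85 kept their call under every alternative, and none reversed. The counts of 2731 higher and 2590 lower became 1746 and 1678 with replicate 1 from its dye-swap array, 1059 and 1017 without moderation, and 1765 to 3001 and 1710 to 2846 with a replicate left out. Without replicate 3 they were 1765 and 1710. At least 2-fold, 183 higher and 181 lower became 450 and 466 with processed signals and with the authors' matrix, 442 and 474 with that matrix centred, and 324 and 353 with normexp offset 0, which shrinks dim ratios less. Mef2 moved from -0.04 to 0.195 with the mean of probes and to 0.730, 0.162 and 0.217 with probes A_09_P013321, A_09_P013326 and A_09_P136280. Without a replicate it ran from -0.077 to 0.032. Lists called went from 3 to 5 with a dye term and to 0 with an estimated correlation, which had little power with 3 replicates. They went to 14 with fry, which does not compare a list with other genes. The share called near the cluster, 58.4% on the arm, was 56.0%, 58.0% and 56.0% among the 50, 100 and 200 nearest genes and no longer passed, with fewer genes inside. Elsewhere the cause was not tested. Aquantile leaves ratios as they are, so it matches by construction. The dye-swap pair as a block could not be fitted, since limma gave a correlation for 0 genes. Seed-site lists, their 8mer version and windows in Mb were not run. Signal over background limits dim genes.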

Other observations

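Families by symbol stem were tested after the lists. Of 15 measured Osi genes, 12 fell and 2 rose (median -0.49, camera adjusted p = 0.00445, and adjusted p = 0.822 with an estimated correlation). Among 18 Nup genes, which name nuclear pore proteins, 12 rose and 1 fell (median 0.27, camera adjusted p = 0.0478, and adjusted p = 0.822 with an estimated correlation). Of 68 families, 4 passed camera, RpL and RpS among them, and 0 passed with both correlations. Camera with an estimated correlation had little power here, so whether members of a family move together is left open.

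Of 5522 tested probes without a gene name, 1104 were higher and 1434 lower in the null, 100 and 148 of them by at least 2-fold.

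Genes at least 2-fold different lay next to each other in 32 neighbouring pairs, against a mean of 13.6 and a highest count of 29 in 10000 shuffles of gene order (permutation p = 0.0001, the smallest they can give). Examples, chosen after their values were seen, are Amy-p with Amy-d (2.73 and 2.66) and Kr with CG30428 (3.46 and at least 3.06-fold). It may be that neighbouring genes differ together. Without pairs sharing a symbol stem 25 remained (permutation p = 0.0024). A count chosen after that, also without genes named by number alone, left 7 pairs against 5.62 (permutation p = 0.33). Some copies told apart by a final letter share no stem here. Amy-p with Amy-d, Cyp12d1-p with Cyp12d1-d, LysB with LysD and LysD with LysE thus stayed in both reduced counts. Neither count removes all tandem copies, so these cannot be told apart from other causes. A differing chromosome segment around the cluster was not decided either: 3.0% of the 100 nearest genes were at least 2-fold different, against 3.7% elsewhere (Fisher's exact test, two-sided, p = 1.00).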
